A study of Mus musculus with 6 samples.

How the data were processed

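RNA sequencing libraries were made from total RNA of mouse embryonic fibroblasts with a TruSeq Ribo-Zero kit, which depletes ribosomal RNA, per the labels' protocols. There were 6 samples, 3 wild-type (WT) and 3 β-actin knockout (KO). Group and replicate number were both taken from the sample titles. Per the submitters' processing notes, FastQC 0.11.5, Trimmomatic and Bowtie2 were used and the genome builds named are mm10 and GRCm38. The tool that counted repeats, the repeat annotation and the treatment of strand are not given in the sources used here.

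The authors deposited, for each sample, estimated counts (fractional counts, per the file names) for rows that each have a repeat name, class and family, without normalization. All values were already whole numbers. How a read that matches several subfamilies was divided is not given in the sources used here. If similar subfamilies share reads, rows of one group can move together for that reason alone, which was not tested. Counts were summed over all genomic copies. Reads from a copy inside an intron or untranslated region of a gene cannot be told apart from transcription that starts in the repeat. The same files hold 67 structural RNA rows (rRNA, tRNA, snRNA and others).

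Counts were analysed in R 4.3.3 with edgeR 4.0.16. Rows with too few counts were removed with filterByExpr, which left 1193 rows and removed 143. Effective library sizes came from TMM, and KO was compared with WT by the quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. Standard errors of log2 fold changes were taken from the test statistic. Levels are CPM of the effective library size, named normalized CPM, given as mean ± SD of 3 libraries. TMM factors ran from 0.423 to 3.13 because rRNA filled between 32.4% and 84.8% of the counts. Levels are therefore relative to the bulk of repeat rows, and a change of all repeats together against the rest of the transcriptome could not be seen. Family totals were summed counts, tested in edgeR with the same effective library sizes, for 58 of 65 families with a mean of at least 10 counts. Repeat lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, variance trend) with a preset correlation of 0.01 between rows. Of 21 lists, 20 had at least 3 tested members, and the list of simple and low-complexity repeats matched no row. No list call held with an estimated correlation, and by fry, which tests whether a list's rows move one way without comparing them with other rows, the calls for structural RNA and ETn/MusD held. Class shares were compared with an exact two-sided permutation test. In the files the replicates of each group differed by far more than sampling noise, with chi-square over degrees of freedom of 186 or more for each pair.

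The tests, the lists, the named rows and all alternatives except those stated otherwise were fixed before the data were examined. Named rows were the 10 largest rises and 10 largest falls among called rows with a mean of at least 50 counts and no overlap between groups, a fixed set of well-known elements, and the 2 rows with the smallest p of each tested list. Of 16 fixed names 12 were present. The absent ones were the LINE-1 names L1Md_T, L1Md_A, L1Md_Gf and L1Md_G. LINE-1 rows with names starting with L1MdTf, L1MdA and L1MdGf were present, but the fixed set did not pick them. Under these rules 55 rows were named. Alternatives were DESeq2 1.42.0 size factors or no scaling in place of TMM, other count filters, leaving out structural RNA or all rows that are not transposable elements, a replicate block, leaving out each library, DESeq2, limma-voom, a minimum change of 1.5-fold, and other settings of the list test. Alternatives built on the rRNA level were added after seeing the data. WT and KO libraries with the same number did not deviate together (correlations of -0.44, -0.39 and 0.02 for numbers 1, 2 and 3). The highest correlation, 0.51, was between WT replicate 1 and KO replicate 2, the libraries lowest in rRNA. The next, 0.34, was between WT replicate 2 and KO replicate 1, those highest in rRNA. Deviations thus went with rRNA share and cannot show that a shared litter or batch was absent. Nothing in the labels says that a number marks one, so the numbers were not used to pair samples.

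The procedure was tested on simulated data with the mean level and spread of each row and the effective library sizes. The rRNA share of each library was not reproduced, so the following rates do not cover the rRNA shares seen here. In 5 simulations of 1193 rows, each with 200 changed rows, 70.6% of 1.5-fold and 89.5% of 2-fold changes were recovered, and 3.61% of calls were unchanged rows. With no changed rows it made 0 subfamily calls, 0 list calls and 1 family call over 5 simulations. The simulated rows varied independently, which real repeat rows do not. The depth of tested rows, a median of 107 counts in WT replicate 2 to 350 in WT replicate 1, limits the precision for rare subfamilies.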

Results

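RNA from repeated DNA was measured in mouse embryonic fibroblasts, the connective-tissue cells cultured from mid-gestation embryos, of 2 genotypes. Wild-type (WT) cells were compared with cells lacking both copies of Actb (KO), the gene of the cytoskeletal and nuclear protein β-actin. The labels give the strain as BALB/c and the embryos as 10.5 days old, and the series describes 3 biological replicates per genotype. Each of the 6 libraries was made from total RNA after removal of ribosomal RNA, and its reads were assigned to rows, of which 1193 had enough counts to be tested and 143 did not, each a repeat subfamily or a class of structural RNA, with its repeat class and family. The rows hold no protein-coding genes, so Actb RNA itself was not analysed here. The rows are genome-wide sums over all copies of a subfamily, without chromosome positions.

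The total per library ranged from 7708630 fractional counts in WT replicate 1 to 19288620 in KO replicate 1, with 17937809 and 15408430 in WT replicates 2 and 3 and 9191049 and 17181225 in KO replicates 2 and 3. Most of this spread was ribosomal RNA. The 3 rRNA rows took 32.4% of the counts in WT replicate 1, 84.1% in WT replicate 2 and 73.7% in WT replicate 3. They took 84.8% in KO replicate 1, 52.9% in KO replicate 2 and 77.0% in KO replicate 3. The exact (Clopper-Pearson) 95% binomial interval was 32.38% to 32.45% in WT replicate 1, the shallowest library, and covers counting error only. Counts outside rRNA were closer together, from 2859992 in WT replicate 2 to 5210011 in WT replicate 1. All levels below are CPM of the effective library size (normalized CPM), which is set by the trimmed mean of M-values (TMM) and not by the rRNA.

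**Figure D1:**
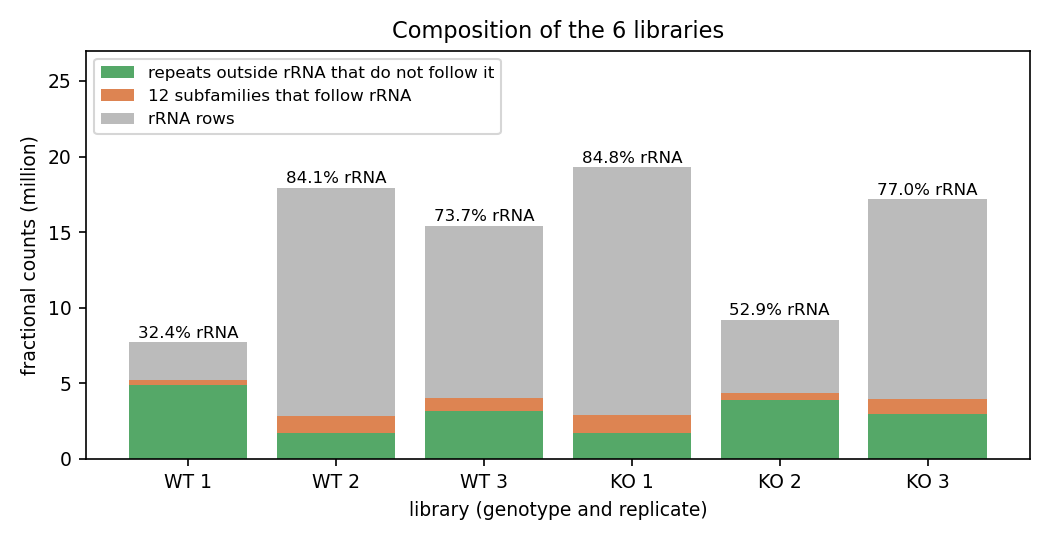
Fractional counts (in units of 1e6, y axis) in each of the 6 libraries (x axis), stacked as rRNA rows, 12 subfamilies whose level followed rRNA, and all other rows, with the rRNA share above each bar. The rRNA share ran from 32.4% to 84.8% and varied within both genotypes.

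The first comparison asked whether the broad composition of repeat RNA differed between the genotypes, and no class passed the test. Among the counts outside structural RNA, LTR elements (endogenous retroviruses and their relatives) took 35.8% ± 7.02 (SD, n = 3) in WT and 37.4% ± 6.66 in KO. SINEs, the short interspersed elements that include B1 and B2, took 37.5% ± 5.83 in WT and 35.1% ± 5.14 in KO. LINEs, the long interspersed elements, took 18.3% ± 1.06 in WT and 19.5% ± 0.749 in KO. DNA transposons took 2.94% ± 0.808 and 2.69% ± 0.708, and satellites 1.62% ± 0.358 and 1.80% ± 0.477. These shares hold the 12 LTR, LINE and SINE subfamilies whose level followed rRNA, and the LTR share was 28.6% in WT replicate 1 and 43.8% in KO replicate 1, the libraries with the least and the most rRNA. The LINE difference, 1.21 percentage points, was larger than the SD of either genotype. Its p-value was the lowest of these, 0.2 in an exact two-sided permutation test, in a design of 3 against 3 samples whose smallest possible p is 0.1. The rRNA share of all counts was 63.4% ± 27.3 in WT and 71.5% ± 16.7 in KO (exact two-sided permutation p = 0.6, n = 3 per group).

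The central comparison asked which repeat subfamilies differ in RNA level between KO and WT cells. KO cells had more RNA of the ETn/MusD retrotransposons, a young group of ERVK endogenous retroviruses, at 1.41 to 1.56 times the WT level in 4 of its 5 rows. They had less RNA from small structural genes: U3, the small nucleolar RNA of pre-rRNA processing, stood at 0.307 of its WT level, U2, a spliceosomal RNA, at 0.453, and 13 tRNA rows were also lower. B2_Mm1a, a young B2 SINE, stood at 0.652 of its WT level. Of 1193 rows tested, 26 were higher and 43 lower in KO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). In 308 tested rows, 25.8%, the 3 KO libraries all lay above or all below the 3 WT libraries, where chance gives 10% on average over splits. Rows are not independent and the share in other splits was not counted, so this excess was not tested. Most changes were small: the median absolute log2 fold change of the 69 called rows was 0.55, and 19 of them changed by at least 2-fold. Leaving out a library reduced the count of calls to 44 without WT replicate 1, 43 without WT replicate 2, 28 without WT replicate 3, 22 without KO replicate 2 and 29 without KO replicate 3, while 69 rows were called without KO replicate 1. Only 55 of the reported rows were among the 69 called without KO replicate 1. In each fit without a single library the 69 reported rows kept their direction. That outcome was nearly fixed in advance, since in all 69 the libraries of the genotypes did not overlap. With 4 libraries, after leaving out WT replicate 1 and KO replicate 2, which had the least rRNA, 9 rows were called. Scaling by total counts, rRNA included, moved the median of all rows by -0.37 and left 0 calls in edgeR, with 3 rows at an unadjusted p under 0.05 (249 as reported). Fold changes below are relative to the TMM scale, and rows with small rises lie below 0 on the total-count scale.

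**Figure D2:**
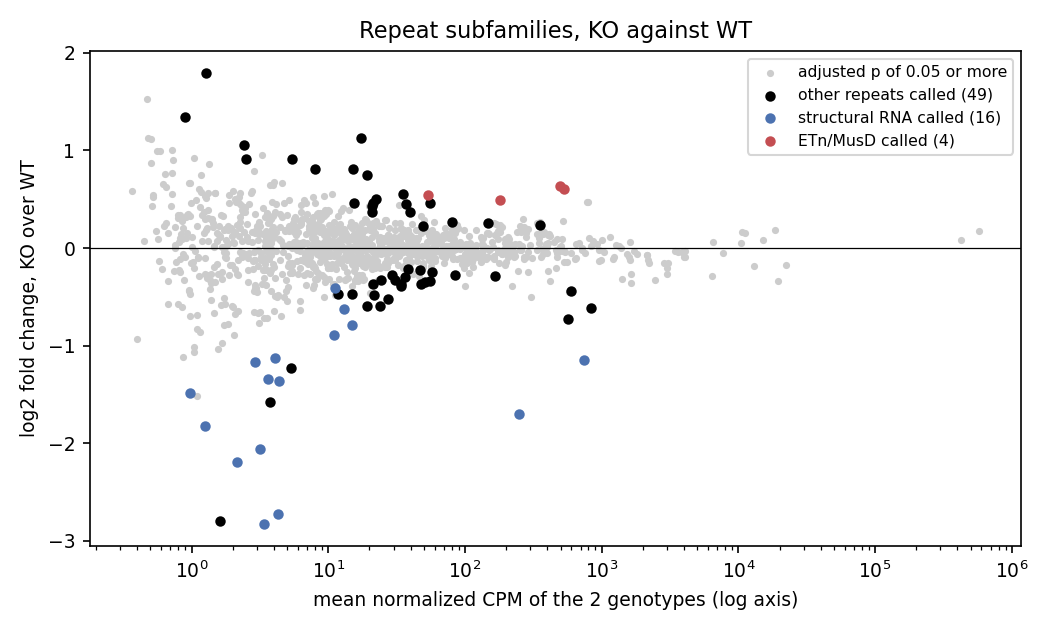
Log2 fold change of KO over WT (y axis) against the mean normalized CPM of the genotypes (x axis, log scale) for the 1193 tested rows, with called rows coloured by group. The 16 called structural RNA rows all lie below 0 and the 4 called ETn/MusD rows all lie above 0.

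ETn/MusD elements had the highest median of the 20 tested lists: 4 of 5 rows rose and none fell, also when adjusted over the list alone. ETnERV-int, an internal region, rose from 389 ± 31.0 to 605 ± 39.8 normalized CPM (mean ± SD, n = 3), a log2 fold change of 0.64 with a standard error of 0.08 (edgeR adjusted p = 0.00474). MMETn-int rose from 421 ± 33.4 to 642 ± 44.1, and ETnERV2-int from 149 ± 10.3 to 209 ± 6.51. Their long terminal repeat RLTRETN_Mm rose from 43.8 ± 0.992 to 63.8 ± 2.79, a log2 fold change of 0.55 with a standard error of 0.05 (edgeR adjusted p = 0.00137). The fifth row, ETnERV3-int, was at 43.5 ± 2.72 in WT and 45.7 ± 2.60 in KO and did not pass (edgeR adjusted p = 0.520). The list as a whole was higher than the other repeats by limma's camera with a preset correlation (median log2 fold change 0.55, adjusted p = 4.34e-06) and lost the call with an estimated correlation (adjusted p = 0.540 with an estimated correlation). Scaled by total counts the list median was 0.20. These rows belong to related elements and may not be independent measurements, since how reads matching several rows were divided is not given in the sources used here. Without WT replicate 1 and KO replicate 2, RLTRETN_Mm stayed past the threshold, whereas ETnERV-int, MMETn-int and ETnERV2-int did not, at log2 fold changes of 0.59, 0.56 and 0.46.

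Other ERVK elements moved in both directions. Over all 277 tested ERVK rows, ETn/MusD included, 14 rose and 7 fell, with a median log2 fold change of 0.02 (camera adjusted p = 0.369). Of the 14 rises, 4 were the ETn/MusD rows above. RLTR46A2, an LTR, had the largest rise among rows with at least 50 counts on average, from 10.9 ± 0.667 to 23.7 ± 3.44 normalized CPM, a log2 fold change of 1.12 with a standard error of 0.12 (edgeR adjusted p = 0.00312). RLTR26B_MM rose to 1.69 times its WT level, but did not pass without WT replicate 1 (log2 fold change 0.73) or without KO replicate 3 (0.78). ERVB7_1-LTR_MM rose from 28.8 ± 0.998 to 42.0 ± 1.28 and RLTR13D3A from 18.4 ± 0.650 to 26.0 ± 0.982. Intracisternal A particles (IAP), the most mobile ERVK group in mice, did not rise: of 25 rows, none rose and 3 fell, 4 when adjusted over the list alone, with a list median of -0.05 (camera adjusted p = 0.175). The rows that fell included IAPEY5_I-int, from 28.8 ± 1.90 to 18.8 ± 1.94, and IAPEY3_LTR, from 22.9 ± 2.33 to 15.3 ± 0.680. The main IAP internal region, IAPEz-int, was at 439 ± 19.2 in WT and 374 ± 12.2 in KO (edgeR adjusted p = 0.0743; it passed with DESeq2, limma-voom, the rRNA covariate and without the rows that followed rRNA, at -0.23), and IAPLTR1_Mm had a log2 fold change of -0.18 (edgeR adjusted p = 0.167). In the MMERVK10C group none of 11 rows passed (median 0.12, camera adjusted p = 0.585). Its members MMERVK10C-int, RLTR10E and RLTR10F had log2 fold changes of 0.12, -0.32 and 0.10. RLTR10E passed without KO replicate 3, at -0.41. On the total-count scale MMERVK10C-int and RLTR10F lay below 0, at -0.21 and -0.24, as did the list median, at -0.27.

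**Figure D3:**
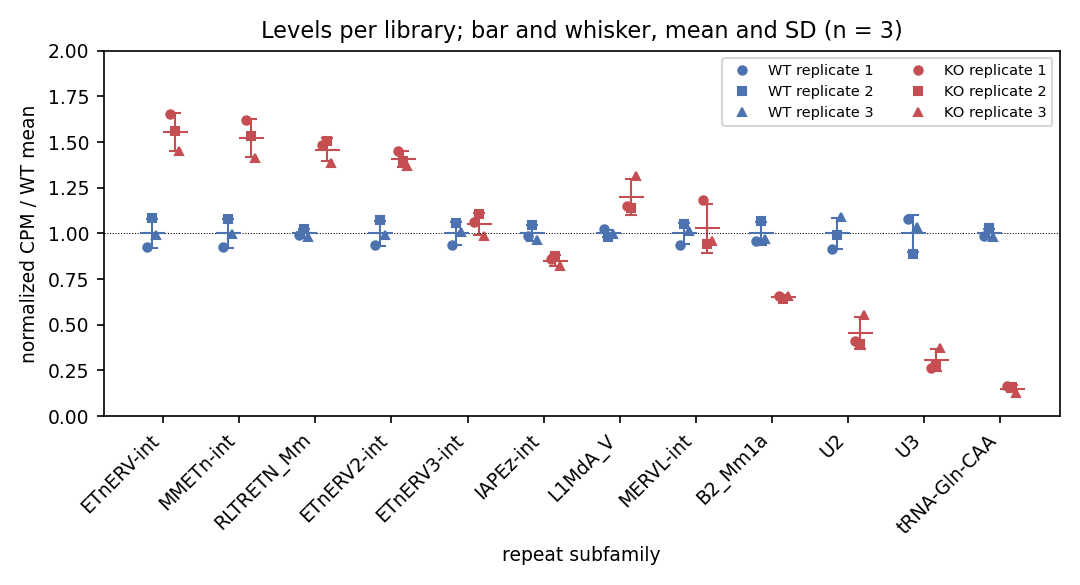
Normalized CPM of 12 subfamilies (x axis) divided by the WT mean of each (y axis, linear from 0), with each library as a point and the mean and SD (n = 3) as a bar and whisker. In ETnERV-int, MMETn-int, RLTRETN_Mm and ETnERV2-int the KO libraries lie above all WT libraries, and in B2_Mm1a, U2, U3 and tRNA-Gln-CAA they lie below all of them.

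Gammaretroviral and ERVL groups had few calls. Of 14 rows of the leukaemia virus, GLN and VL30 groups, none rose and 2 fell (median -0.09, camera adjusted p = 0.163). MMERGLN-int fell from 683 ± 40.8 to 504 ± 36.8 normalized CPM, and RLTR4_MM-int, the internal region of murine leukaemia virus elements, from 181 ± 6.96 to 149 ± 5.36. MMERGLN-int did not pass without WT replicate 2 or 3 (-0.40 and -0.43) or KO replicate 2 or 3 (-0.44 and -0.39). RLTR4_MM-int did not pass without any single WT replicate (-0.27, -0.27 and -0.31) or KO replicate 2 or 3 (-0.28 and -0.26). MMVL30-int, the retrovirus-like VL30 element, was at 2749 ± 366 in WT and 2187 ± 196 in KO and did not pass (edgeR adjusted p = 0.188), but passed with DESeq2 (-0.33) and with the rRNA level as a covariate (-0.36), as did the list (median -0.12) and MT2B2 (-0.31) with that covariate. None of 8 rows of the MERVL group, which is active in the early embryo, passed (median -0.05, camera adjusted p = 0.552): MERVL-int was at 101 ± 5.80 in WT and 103 ± 13.5 in KO, MT2A at 279 ± 7.06 and 262 ± 3.13, and MT2B2 at 7024 ± 960 and 5780 ± 452. MT2_Mm, the LTR of MERVL, ranged too widely for a comparison, at 495 ± 451 in WT and 430 ± 326 in KO, and followed the rRNA level of the library. Over all ERVL rows 1 of 104 rose and none fell (median 0.03, camera adjusted p = 0.441). That row was LTR80A, from 0.517 ± 0.223 to 2.05 ± 0.241 normalized CPM, and LTR82A, with a log2 fold change of 0.55, did not pass (edgeR adjusted p = 0.0571) but did without KO replicate 1, at 0.61, and at 0.55 to 0.59 with DESeq2 or its size factors, the rRNA covariate and without the rows that followed rRNA. LTR80A, with 2 to 39 counts per library, did not pass without WT replicate 3 (1.87), KO replicate 2 (1.83) or KO replicate 3 (1.84). Of 103 MaLR rows none rose and 5 fell, 2 when adjusted over the list alone, with MTE2b-int and MLT1G1 at log2 fold changes of -0.39 and -0.27. MTE2b-int did not pass without WT replicate 1 (-0.37), KO replicate 2 (-0.36) or KO replicate 3 (-0.40), and MLT1G1 not without WT replicate 2 (-0.27), WT replicate 3 (-0.24), KO replicate 2 (-0.31) or KO replicate 3 (-0.26). The MaLR list median was 8.45e-05, its mean -0.01 and its camera direction downward (adjusted p = 0.601). Of 110 ERV1 rows 1 rose and 4 fell (median 0.03, camera adjusted p = 0.731).

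Rows of the LTR class were split by name into those ending in -int, all internal regions, and the others. The others were mostly LTRs but held internal regions with other names, among them ERVB4_1-I_MM and ERVB4_2-I_MM, which both rose. Of these 505 other rows 13 rose and 8 fell, with 10 and 2 adjusted over the list alone (median 0.03, camera adjusted p = 0.158), and of 126 rows ending in -int 4 rose and 8 fell, with 8 and 9 adjusted over the list alone (median 0.000778, mean 0.03, camera direction downward, adjusted p = 0.777). The list of other rows passed in 3 of 18 alternatives, among them without WT replicate 1 (median 0.06) and without KO replicate 1 (0.03). Of the LTRs known to be used in embryonic stem and trophoblast cells, chosen as markers of other cell types, 1 of 25 rose, 3 when adjusted over the list alone, and none fell (median 0.04, camera adjusted p = 0.208). The row that rose was RLTR13D3A. RLTR45-int was at 81.6 ± 4.43 in WT and 93.4 ± 2.61 in KO (edgeR adjusted p = 0.0649).

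LINE-1 rows leaned upwards by small amounts. Of the 25 mouse LINE-1 rows with names starting with L1Md, a list set by name and not by age or activity, 23 had a fold change above 0. Of them 1 rose past the threshold and none did when adjusted over the list alone. L1MdA_V, the row that rose, went from 72.8 ± 1.57 to 87.5 ± 7.16 normalized CPM (edgeR adjusted p = 0.0462). L1MdF_II was at 83.1 ± 3.41 and 95.5 ± 6.72 and did not pass (edgeR adjusted p = 0.0952). The L1MdTf and L1MdGf rows of the list did not pass either. The list median was 0.15 (camera adjusted p = 1.88e-05, and adjusted p = 0.706 with an estimated correlation). Of the 124 other LINE-1 rows, 2 rose and none fell, with none adjusted over the list alone (median 0.07, camera adjusted p = 0.00585, and adjusted p = 0.540 with an estimated correlation). They were L1ME3B and L1Lx_IV, at log2 fold changes of 0.23 and 0.24. The calls of L1MdA_V, L1ME3B and L1Lx_IV were lost when any single library was left out, with log2 fold changes of 0.19 to 0.30, 0.20 to 0.26 and 0.22 to 0.25. On the total-count scale they lay below 0, at -0.14, -0.15 and -0.14, and L1MdF_II, at -0.17, did too. On that scale the medians of both LINE-1 lists also lay below 0, at -0.22 for the L1Md rows and -0.31 for the other LINE-1 rows, and neither list passed. L1MdF_II passed without KO replicate 1, at 0.25. In these lists 3 L1Md rows and 2 other LINE-1 rows followed the rRNA level of the library.

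All 5 B2 rows had fold changes below 0, with 1 fall past the threshold over all rows and 3 adjusted over the list alone (median -0.26, camera adjusted p = 0.0102, and adjusted p = 0.706 with an estimated correlation). B2_Mm1a fell from 1004 ± 60.8 to 655 ± 10.05 normalized CPM, a log2 fold change of -0.62 with a standard error of 0.07 (edgeR adjusted p = 0.00429), and did not pass without WT replicate 1 and KO replicate 2 (-0.62). The B2 list did not pass without WT replicate 2 (median -0.25). B2_Mm1t was at 1834 ± 98.8 in WT and 1432 ± 70.9 in KO, and B2_Mm2 at 3297 ± 74.2 and 2750 ± 129, and neither passed. Both passed with DESeq2, with limma-voom, with the rRNA level as a covariate and without the subfamilies that followed rRNA, at log2 fold changes of -0.36 to -0.37 and -0.26 to -0.27, and B2_Mm1t also with a mean of at least 50 counts. None of 16 B1 rows passed, all with fold changes below 0 (median -0.10, camera adjusted p = 0.0269, and adjusted p = 0.706 with an estimated correlation). The B1 list did not pass without WT replicate 2 (-0.07), WT replicate 3 (-0.09), KO replicate 2 (-0.09) or KO replicate 3 (-0.06). B1_Mm was at 1040 ± 39.8 and 952 ± 22.6, and B1F2 at 1001 ± 38.5 and 916 ± 55.6. None of the 4 B4 rows passed (median -0.06, camera adjusted p = 0.601), including ID_B1 and RSINE1 at log2 fold changes of -0.19 and -0.09. ID_B1 passed with the rRNA level as a covariate (-0.21).

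Structural RNA had the most falls of the 20 tested lists. Of 58 rows tested, 16 fell and none rose, and 31 fell when adjusted over the list alone. The list median was -0.58 (camera adjusted p = 1.19e-17, and adjusted p = 0.132 with an estimated correlation). U3 fell from 381 ± 38.7 to 117 ± 22.3 normalized CPM, a log2 fold change of -1.70 with a standard error of 0.14 (edgeR adjusted p = 0.000808). U2 fell from 1015 ± 88.0 to 460 ± 89.0, and U8, another nucleolar RNA of pre-rRNA processing, from 6.20 ± 1.63 to 2.47 ± 0.892. Among tRNA rows 13 of 39 fell: tRNA-Gln-CAA went from 7.44 ± 0.201 to 1.12 ± 0.153, tRNA-His-CAY from 14.1 ± 0.671 to 7.70 ± 1.28, tRNA-Lys-AAA from 18.9 ± 2.50 to 10.7 ± 1.42, tRNA-Asn-AAC from 5.14 ± 0.878 to 2.09 ± 0.520 and tRNA-Thr-ACY from 5.74 ± 0.556 to 2.46 ± 0.664. These tRNA rows rest on few reads, with a mean of 52 to 215 counts per library, and 3 of them and U8 depended on single libraries. U8 did not pass without any 1 library (-1.04 to -1.72). tRNA-Asn-AAC did not pass without WT replicate 3 (-1.19), KO replicate 2 (-1.12) or KO replicate 3 (-1.42), and tRNA-Lys-AAA not without WT replicate 3 (-0.79) or KO replicate 2 (-0.70). tRNA-Thr-ACY did not pass without WT replicate 2 or 3 (-1.07 and -1.09) or KO replicate 2 or 3 (-1.29 and -1.16). The abundant 7SK and 7SLRNA rows did not pass, with log2 fold changes of -0.17 ± 0.16 and -0.34 ± 0.16 (standard error). The rRNA rows did not pass either: LSU-rRNA_Hsa was at 412068 ± 403196 in WT and 435141 ± 366306 in KO.

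Satellites and ancient repeats showed few calls. None of 7 satellite rows passed (median 0.03, camera adjusted p = 0.558). GSAT_MM, the major satellite of pericentromeric heterochromatin, was at 667 ± 108 in WT and 925 ± 232 in KO, with no overlap between the genotypes (edgeR adjusted p = 0.188), and SYNREP_MM at 652 ± 106 and 905 ± 227. Of 275 rows of old DNA transposons, L2, MIR and CR1 elements, 4 rose and 8 fell (median -0.02, camera adjusted p = 0.208). This list, of ancient interspersed repeats, passed without structural RNA (-0.03), with transposable elements only (-0.04) and without the 2 libraries lowest in rRNA (-0.06). Those that rose included MamTip2b, Charlie22a and Tigger12c, at 1.88, 1.75 and 1.75 times the WT level. UCON80 and UCON35, in the same list, fell to 0.144 and 0.426 of the WT level. MARE6, the only row of the LINE family L1-Tx1, fell to 0.335 of its WT level. Several of these calls ended without 1 library: MamTip2b without WT replicate 3 (0.87), KO replicate 2 (0.92) or KO replicate 3 (0.93), and Tigger12c without WT replicate 1 (0.68), KO replicate 2 (0.82) or KO replicate 3 (0.83). UCON35 did not pass without WT replicate 2 (-1.20), WT replicate 3 (-1.16) or KO replicate 3 (-1.04), nor MARE6 without WT replicate 3 (-1.57) or KO replicate 2 (-1.32).

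Counts summed by repeat family asked whether whole families changed, and 6 of 58 families passed the test. The tRNA family fell from 215 ± 11.5 to 140 ± 4.54 normalized CPM (log2 fold change -0.62, standard error 0.06, edgeR adjusted p = 9.18e-07). The snRNA family fell from 2751 ± 113 to 1574 ± 305 and the scRNA family, mostly BC1_Mm, from 1989 ± 95.4 to 1670 ± 74.2. None of the 4 tested scRNA rows passed on its own, with BC1_Mm at a log2 fold change of -0.26 (edgeR adjusted p = 0.131). Without BC1_Mm the scRNA family was at -0.18 (edgeR adjusted p = 0.0433). The hAT-Tip100 DNA transposons fell from 914 ± 65.6 to 629 ± 56.1. A single row, FordPrefect, held 73.3% of the counts of that family, and without it the log2 fold change was -0.02 (edgeR adjusted p = 0.870). FordPrefect was singled out after its values were seen. L1-Tx1 fell with its only row, and the Gypsy-related LTR family rose from 44.2 ± 2.87 to 52.3 ± 1.81 (edgeR adjusted p = 0.0496), with a log2 fold change of 0.24 (standard error 0.07). Without its most abundant row, MamGyp-int, the log2 fold change was 0.26 with a larger standard error, 0.09, and did not pass (edgeR adjusted p = 0.117). It was the only family that rose, and 0 families rose with DESeq2 size factors, without WT replicate 3, without KO replicate 2 or without KO replicate 3. Family totals of L1, ERVK, ERVL, ERV1, MaLR and B4 held rows that followed rRNA. The log2 fold changes of the ERVK, L1 and MaLR totals had standard errors of 0.50, 0.33 and 0.29. A moderate change of these totals could therefore not be seen.

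In 12 transposable element subfamilies the level followed the rRNA level of the library within both genotypes, with slopes of 0.53 to 1.05 on log2 LSU rRNA, and none of them was called between the genotypes. They took 5.96% of the counts outside rRNA in WT replicate 1 and 41.5% in KO replicate 1.

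**Figure D4:**
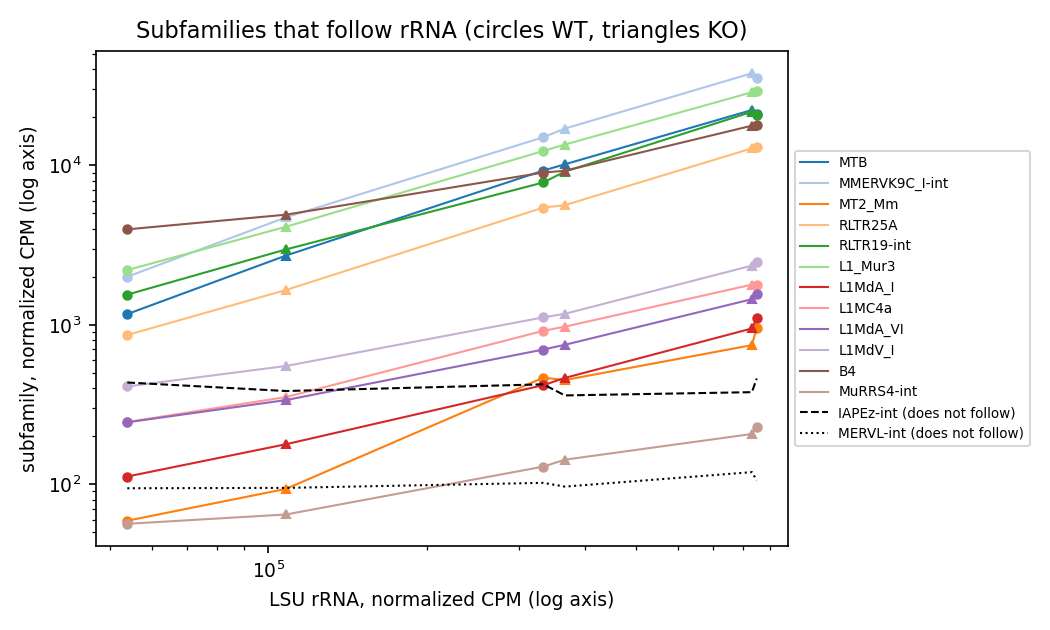
Normalized CPM of the 12 subfamilies that followed rRNA (y axis, log scale) against normalized CPM of LSU rRNA (x axis, log scale), with circles for WT and triangles for KO libraries and lines joining the libraries in order of LSU rRNA. IAPEz-int and MERVL-int, in black, lay between 360 and 461 and between 94.2 and 119 normalized CPM across the libraries.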

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

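Alternatives that use the rRNA level or leave out rows that followed it were chosen after seeing the data; all others were planned. DESeq2 size factors (64), no low-count filter (67), a mean of at least 50 counts (52), DESeq2 (74) and limma-voom (63) kept the number of called subfamilies within 1.5 times the reported 69, as did rRNA as a covariate (94) and leaving out the rows that followed it (83). The called rows were not all the same. In the order given, these alternatives still called 63, 65, 50, 54, 55, 64 and 64 of the reported 69. The count was 41 without structural RNA and 41 with transposable elements only, where fewer rows were tested and the share called higher rose from 37.7% to 48.8% and 43.9%, 33 with at least a 1.5-fold change and 9 without the 2 libraries lowest in rRNA. The replicate block called 24, a loss in a design with fewer residual degrees of freedom, and the samples share only a number. Leaving out each library gave 22 to 69 subfamilies, 4 to 7 families and 4 to 7 lists. Scaling by total counts only, which includes the rRNA, shifted the median of all rows by -0.37 and gave 0 subfamilies (3 at an unadjusted p under 0.05), 0 families and 2 lists; under it L1MdA_V, L1ME3B and L1Lx_IV turned to -0.14, -0.15 and -0.14. The block gave 4 families and 5 lists. Families numbered 2 with transposable elements only, where the 3 called families of structural RNA were absent, and 14 with rRNA as a covariate, where the cause was not tested. Of the 6 lists called, 0 passed with an estimated correlation and 2 with fry. In class shares of counts, rRNA differed by 8.15 points (KO minus WT), and by -7.34 to 18.5 points without single libraries. Over all alternatives, 832 values of named subfamilies stayed on their side of the threshold, some uncalled ones with a change of sign, 163 lost a call, 24 gained one and the 3 above turned; for lists, by the direction of the set test against other rows and not by the sign of the median, these were 330, 20, 7 and 0. Depth limits what can be seen for rare rows, such as UCON80 at 3 to 74 counts per library.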

Other observations

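All tests of explanations in this part were chosen after the results were seen, except the counts over other splits of the samples. ETn/MusD was not the only ERVK group with several rises. Of 14 rows of the ERVB4 and ERVB7 elements, 5 rose and none fell, in a grouping made after these values were seen and not tested as a set. ERVB7_2B-LTR_MM went from 31.0 ± 1.98 to 42.5 ± 1.46 normalized CPM (SD, n = 3), and ERVB4_2-I_MM had a log2 fold change of 0.46. ERVB4_1B-I_MM, the most abundant of these rows, was lower in KO at a log2 fold change of -0.32 and did not pass (edgeR adjusted p = 0.172). YREP_Mm, a repeat named for the Y chromosome, was at 3212 ± 125 in WT and 2787 ± 92.1 in KO. The family annotated as Y-chromosome, with 1 row, was at 138 ± 4.17 in WT and 125 ± 6.36 in KO. Rows hold no positions, so neither value shows that copies on the Y chromosome gave these reads.

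In 12 transposable element subfamilies the level followed rRNA across libraries of both genotypes, as in MMERVK9C_I-int at 2002 normalized CPM in WT replicate 1, with the least rRNA, and 35345 in WT replicate 2. A candidate explanation is that rRNA reads were counted under these subfamilies. Of the rows picked by their slope in WT libraries alone, 11 in number, the median slope on LSU rRNA in the KO libraries was 0.95 (0.62 to 1.04, where 1 is proportional). A scaling error of the rRNA-rich libraries would give all rows 1 slope, whereas the picked rows exceeded the others by 0.95 (bootstrap 95% interval 0.71 to 1.02). That interval came from resampling the picked rows and leaves out the spread between libraries. The sequences of the repeats were not compared with rDNA, and no biological explanation was tested.

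The falls of small structural RNAs may reflect the RNA preparation or the cells. A side effect of the rRNA share is argued against only weakly: with the rRNA level as a covariate the list median was -0.54, against -0.58 without it. LSU rRNA differed little between the genotypes (log2 fold change 0.08, standard error 0.96), so the covariate had little room to move the median. A fall of RNA polymerase III transcripts alone is argued against by U2 and U3, RNAs made by polymerase II, which each passed the test between genotypes. This holds if their reads come from polymerase II genes, which was not tested, since rows sum all genomic copies. U8, also made by polymerase II, passed but lost the call when any single library was left out. U1, U4, U5 and U13 lay below 0 and did not pass. The median of these 7 rows was -0.54, in a set formed after those falls were seen. A loss of shorter RNAs from the KO libraries stays open. Over 15 small RNA rows of 87 to 331 nucleotides, the log2 fold change had a Spearman rho of -0.20 with gene length in the GRCm38 annotation (permutation p = 0.477). The Pearson r was -0.13 (permutation p = 0.640), or -0.56 without the 2 most extreme lengths, across rows that are not independent replicates. These 15 rows held no tRNA row, so the correlation cannot speak for tRNA. The 39 tRNA rows had a median of -0.78, with 37 below 0, against -0.23 for the 8 polymerase III rows outside tRNA. Small RNAs are poorly captured by such libraries, and an effect of genotype itself stays open too, untested.

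For ETn/MusD, a shift of reads between rows of the group would lower some of its rows, whereas all 5 lay above 0. Their summed count rose by a log2 fold change of 0.58 (95% interval 0.37 to 0.79), which follows from those rows and adds no separate evidence. The sum cannot show whether reads were counted in more than 1 row. A rise of ERVK elements in general by a like amount is argued against by all 272 ERVK rows outside ETn/MusD, with a median of 0.00718 (bootstrap 95% interval -0.02 to 0.05), while a rise shared with some of them stays open. The interval came from resampling rows and leaves out the spread between libraries. With the rRNA level as a covariate the ETn/MusD list median stayed at 0.55, where the covariate likewise had little room to move it. What stays open is whether the rise may come from many copies or from a few, such as insertions that differ between the embryos from which the cells came, since counts per copy were not used here, and whether genotype is the reason.

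The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split called 69 subfamilies, and the highest of the other splits called 0; 1 of 10 splits reached the real count. For family totals the real split called 6 and the highest other 0, again 1 of 10. For lists the real split called 6, but 4 of 10 splits reached that count and the highest other called 11, namely WT replicate 1 with KO replicates 2 and 3 against the rest, so counts of lists from the preset correlation carry little weight here.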
